A study of Homo sapiens with 6 samples.

How the data were processed

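K562 is an established cell line grown from a chronic myelogenous leukaemia. Per the labels, wells were plated in triplicate at 500000 to 800000 cells per mL and exposed for 3 h to DMSO, the vehicle, or to 25 nM CA, which the series title names as cortistatin A, an inhibitor of the Mediator kinases CDK8 and CDK19. Total RNA was extracted with an RNeasy Plus Micro kit or with TRIzol, and the labels do not say which was used for which sample. From 100 ng of total RNA, biotinylated cRNA was prepared with the 3' IVT Express kit, a labelling method that starts at the poly(A) tail, and hybridised to Affymetrix Human U133 Plus 2.0 arrays. The labels give no batch and no date.

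The authors deposited 1 table of log2 expression values for 54675 probe sets on 6 arrays, 3 DMSO and 3 CA. Per the submitters' processing notes the values were made with RMA in the affy package, with no version given. RMA subtracts background, gives all arrays the same distribution of probe intensities, and summarises the probes of each probe set. It thereby sets the arrays to a common overall level, so a change shared by most transcripts is not visible in these values, and small fold changes of dim probe sets are compressed. Whether the arrays were processed together with others is not stated. Probe level data were not used here. The number of arrays limits the precision: with 3 against 3 the median standard error of a log2 change was 0.07. Each array correlated with every other at 0.997 to 0.998 across probe sets, and the array medians lay between 3.47 and 3.52. On the second principal component CA array 1 lay at -19.0, away from the other 5 arrays.

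Left out were 62 control probe sets, which were used separately to look at labelling. A probe set was tested if its mean over the 6 arrays was at or above the median of such means, 3.49 on the log2 scale, which kept 27307 probe sets. Genes were named from the platform annotation. Of the probe sets other than controls, 41091 had 1 symbol, 1801 had several and 11721 had none in that table. No gene was named from a probe set with several symbols, and a probe set without a symbol is unnamed here, not without a gene. Of the probe sets with 1 symbol, 41037 were found by gene ID in a current RefSeq gene table, and 0 symbols differed from it. A gene was represented by the tested single-symbol probe set with the highest mean over the 6 arrays, a choice that does not use the groups. That gave 12810 measured genes.

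CA was compared with DMSO by a linear model per probe set with moderated variance (lmFit and eBayes in limma 3.58.1, R 4.3.3), 2-sided, with no block. Benjamini-Hochberg adjusted p under 0.05 over all 27307 probe sets was the threshold, and "called" below means past it. Positive log2 changes are higher in CA. Errors of changes are 95% confidence intervals or standard errors (SE) from the model, and errors of group means are standard deviations (SD, n = 3). The p values of this model measure the spread between wells of this experiment.

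Before the data were examined, 28 gene lists were written from textbook knowledge, covering the Mediator, signalling responses, blood lineages, cell cycle, metabolism, stress, transcription and other cell types. Members were counted as called over all probe sets and, separately, adjusted over the list alone. The adjustment over the list alone corrects neither for the 28 lists nor for the other probe sets, so it is the weaker threshold. SMAD6 and H2AC8, which passed it, had limma adjusted p of 0.395 and 0.391 over all probe sets. Each list was compared with the other measured genes by camera with its preset correlation of 0.01, adjusted over the 28 lists. Camera with a correlation estimated from the arrays and fry were run as alternatives. Unlike camera, fry tests the members of a list against no change, not against the other genes. The number of list members with an unadjusted p under 0.05 was compared with 10000 random lists of genes matched on signal in 20 bins. That comparison draws genes, not arrays, so its p takes list members as independent and does not measure the spread between wells. Genes named were fixed by a rule: all measured members of the Mediator kinase module; the 10 called genes with the largest change in each direction whose CA arrays all lay on 1 side of the DMSO arrays; where fewer than 10 were called, up to 5 further genes by smallest p; and from each list up to 4 called members, or its brightest member where none was called. Other genes named below were chosen after their values were seen. These are the members that passed when adjusted over the list alone or in the fit with a trend, genes called only on another probe set, histone genes outside the list, and list members of the p53, megakaryocyte and G2/M lists.

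Single values such as control probe set signals were compared by exact 2-sided permutation tests, for which 3 against 3 arrays allow no p below 0.1. The tests were checked on simulated data of the same size, with noise drawn independently for each probe set from the moderated variances. In all, 200 probe sets were altered, in equal parts by 1 or by 0.5 log2 units. Of those altered by 1, 99% were called, and of those altered by 0.5, 75%, with 8 false calls. The real arrays gave 26 calls, and with fewer calls the adjusted threshold is stricter, so these shares need not hold there. For example, TGIF1, with a fitted change of 0.53, was not called by limma (adjusted p = 0.0817). On simulated arrays with no difference, 0 probe sets were called. A simulated list of 30 genes shifted by 0.1 was called, and 0 of 28 unshifted lists were. The simulated genes were not correlated, so this does not check the list test on genes that move together.

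Alternatives were no filter, a filter at the 75th percentile, quantile normalisation again, centring on the median, a prior variance that depends on the mean signal (trend), the same with robust estimation, array weights, the replicate number as a block, each array left out in turn, adjusted p thresholds of 0.1 and 0.01, leaving out probe sets marked as shared between transcripts (suffixes _x_at and _s_at), and the mean of all probe sets of a gene. Of these, leaving out shared probe sets was planned for counts of probe sets and the mean for counts of genes, and both were run on the other results after the data were examined. Added after the data were examined was the 3'/5' ratio of control transcripts as a covariate, as the mean over actin, dap and thr. These controls differed most between the groups (-0.24, -0.24 and -0.32), so the covariate largely follows the treatment. Left out of it were GAPDH, lys and phe (-0.03, 0.03 and -0.03). Also added after the data were examined was scaling to the 3' or to the 5' probe sets of the exogenous polyadenylated controls. These are RNAs of bacterial genes mixed into each sample. The labels do not state at which step, or in what proportion to cells or RNA, these were added.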

Results

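The experiment asked which transcripts change when K562 leukaemia cells, which carry the BCR-ABL1 fusion kinase, are exposed for 3 h to 25 nM of the Mediator kinase inhibitor cortistatin A (CA). Expression was measured on 6 arrays, 3 from wells with CA and 3 from wells with DMSO. Values are RMA log2 signals, and 27307 probe sets representing 12810 named genes were bright enough to be tested.

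Transcripts of EGR1, TXNIP and DNAJB4 were lower on the CA arrays and those of 8 genes were higher, among them MYC, GFI1B, BHLHE40, TNFAIP3, MSMO1 and CISH. The largest change was a 3.49-fold fall of EGR1, an immediate early zinc finger transcription factor, from 7.84 to 6.04 on the log2 scale. TXNIP, an arrestin family protein that binds thioredoxin and restrains glucose uptake, fell 2.24-fold, and DNAJB4, a co-chaperone of HSP70 proteins, fell 1.53-fold. The rises were smaller than the falls of EGR1 and TXNIP. They ran from 1.37-fold for CISH, a STAT5-induced inhibitor of cytokine signalling, to 1.72-fold for BHLHE40, a basic helix-loop-helix repressor. For each of these 11 genes all 3 CA arrays lay on the same side of all 3 DMSO arrays.

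In log2 units, EGR1 changed by -1.80 (95% confidence interval -2.09 to -1.51, adjusted p = 0.0152), TXNIP by -1.17 (-1.26 to -1.07, adjusted p = 0.00115) and DNAJB4 by -0.61 (-0.73 to -0.49, adjusted p = 0.0235). BHLHE40 rose by 0.78 (0.62 to 0.94) and LRATD1 by 0.67 (0.54 to 0.80). MSMO1, a sterol oxidase of cholesterol synthesis, rose by 0.62 (0.50 to 0.75). TNFAIP3, the ubiquitin-editing inhibitor of NF-kappaB signalling also called A20, rose by 0.51 (0.41 to 0.62), and the growth regulator MYC, already bright in DMSO at 11.22, rose by 0.50 (0.41 to 0.60). These 5 genes shared an adjusted p of 0.0235. GFI1B, a repressor needed for red cell and platelet development, rose by 0.57 (0.43 to 0.70, adjusted p = 0.0437). RHOH rose by 0.52 (0.39 to 0.65) and CISH by 0.46 (0.34 to 0.57), both at an adjusted p of 0.0455.

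**Figure D1:**
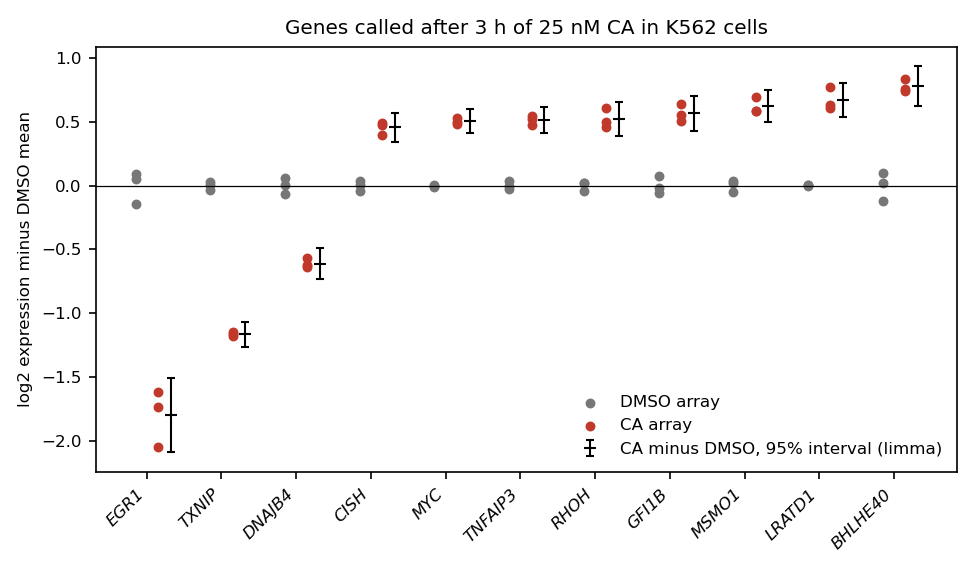
Log2 expression of the 11 called genes on each array, minus the mean of the 3 DMSO arrays, with DMSO arrays in grey and CA arrays in red; black marks are the fitted CA minus DMSO change with its 95% confidence interval. EGR1 and TXNIP lie below -1 on every CA array, and the 8 genes that rose lie between 0.46 and 0.78 in the fitted change.

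Over all probe sets, 26 were called, 14 higher and 12 lower in CA. All 26 were changed by at least 1.2-fold and 18 by at least 1.5-fold, of which 7 rose and 11 fell. Changes of 2-fold or more were 4 falls and 0 rises, and these 4 probe sets were those of EGR1 and TXNIP. All 3 tested probe sets of EGR1, all 3 of TXNIP, both of TNFAIP3 and both of GFI1B were called. For BHLHE40 and DNAJB4 it was 1 of 2, and for CISH and LRATD1 1 of 3, with the others in the same direction. The other LRATD1 probe sets had 0.26 and 0.38. MYC, MSMO1 and RHOH each had 1 tested probe set. The called probe sets also held 1 of 2 for SAMSN1 (0.41), 1 of 3 for CPEB4 (0.59) and 1 of 11 for the nuclear non-coding RNA MALAT1 (-0.58), each other than the brightest of its gene. Of the 11 MALAT1 probe sets, 10 had a lower fitted value in CA. A further 6 called probe sets had no symbol or several and are not named. At an unadjusted p under 0.05 there were 2542 probe sets, where chance alone gives 1365, and 15.6% of probe sets had CA and DMSO arrays that did not overlap, where chance gives 10%.

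The number of calls depended on the variance model and on the arrays. With a prior variance that follows the mean signal, an alternative chosen in advance, 285 probe sets were called, 180 higher and 105 lower, and 157 genes, 94 higher and 63 lower, including the 11 above. Without probe sets marked as shared between transcripts, 1 probe set and 0 genes were called by limma, with 1426 probe sets at an unadjusted p under 0.05. Of the 11 genes, 7 are represented by shared probe sets. The other 4, MSMO1, GFI1B, DNAJB4 and RHOH, lost their calls as well, at adjusted p of 0.0504 to 0.0587. Their probe sets and fitted changes stayed the same, so only the SE and the adjustment differed. LRATD1, then read from another probe set, had 0.26 (adjusted p = 0.429). With quantile normalisation again or centring, CISH (0.0600 and 0.0512) and RHOH (0.0673 and 0.0512) were above the threshold. Their fitted changes there were 0.464 and 0.473 for CISH, against 0.458 in the main fit, and 0.528 and 0.539 for RHOH, against 0.523. Without DMSO array 1, 2 or 3 the count fell from 26 to 2 each time, and without CA array 1, 2 or 3 it was 5, 3 and 5. CA array 1 stood apart on the second principal component, which held 24.4% of the variance, at -19.0 against 0.338 to 7.20 for the other 5 arrays, and correlated no more closely with its own group than with DMSO (0.997 each). TXNIP was called in all 6 of these fits and EGR1 in 2, those without CA array 1 and CA array 3. The other called genes were called in 0 of them, with adjusted p between 0.0916 and 0.287 and fitted changes that kept their direction.

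Scaling the arrays to the exogenous polyadenylated control RNAs gave a shift that depended on the end of the control probed. Their 3' probe sets, all lower in CA, would add 0.18 to every log2 change and move the median over all probe sets from -0.01 to 0.18. Their 5' probe sets, of which dap and thr were higher and lys and phe lower in CA, would add 0.04. The labels do not say whether the controls were added per cell or per amount of RNA, so these scalings are given as alternatives only. Changes are therefore given relative to the other transcripts on the RMA scale. On the 3' control scale EGR1, TXNIP and DNAJB4 were still lower in CA, at -1.62, -0.98 and -0.43, while falls smaller than 0.18 would be rises.

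Just short of the threshold, the further genes with the smallest p were HEXIM1, PPP1R10, DNAJB1, SERTAD1 and TNFRSF12A on the lower side and TMEM158, IL6, RCL1, CHST2 and TGIF1 on the higher side. HEXIM1, the inhibitor of the elongation kinase P-TEFb, had a log2 change of -0.45 (SE 0.05, adjusted p = 0.0704). PPP1R10, a nuclear regulator of protein phosphatase 1, had -0.51 (SE 0.06, adjusted p = 0.0723). IL6 had 0.51 (SE 0.06, adjusted p = 0.0723) at a low signal of 4.25 in DMSO, and TGIF1, a repressor of TGF-beta signalling, had 0.53 (SE 0.07, adjusted p = 0.0817). All 10 of these genes had adjusted p between 0.0695 and 0.0819.

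The genes encoding the target of the compound did not pass the test. CDK8 changed by -0.07 (95% confidence interval -0.18 to 0.05) and CDK19 by -0.09 (-0.23 to 0.05). The other measured members of the Mediator kinase module were CCNC at 0.00, MED12 at -0.04, MED13 at -0.03 and MED13L at 0.02. None of the 6 was called by limma, with adjusted p between 0.707 and 0.998, and 0 had an unadjusted p under 0.05. The 23 measured subunits of the core Mediator also gave 0 calls and 2 at an unadjusted p under 0.05, their median change was -0.04, and MED28, the brightest, changed by 0.04.

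In the counts that follow, members at p under 0.05 are those before adjustment. Members said to pass over the list alone are corrected neither for the 28 lists nor for the other probe sets. Over all 12810 measured genes the share at p under 0.05 was 8.61%. Of the 28 lists fixed in advance, 7 lay higher and 4 lower in CA than the other measured genes by camera. None of the 11 passed with a correlation estimated from the arrays, where their adjusted p lay between 0.175 and 0.515. With fry, which does not compare a list with the other genes, 7 of them passed. Those that did not pass by fry were ribosome biogenesis (adjusted p = 0.0543), cholesterol and fatty acid synthesis (0.134), TGF-beta and BMP targets (0.314) and G2/M (0.347). With the 3'/5' ratio of actin, dap and thr as a covariate, chosen after the data were examined, 2 of the 11 stayed called. These were STAT5 targets (0.000556) and core histones (0.00942), and the other 9 had adjusted p by camera between 0.0911 and 0.949. Without probe sets marked as shared between transcripts 2 of the 11 stayed called, ribosome biogenesis and G1/S, and 9 lost their call, at adjusted p between 0.0572 (core histones, megakaryocyte, p53 and heat shock) and 0.629 (TGF-beta and BMP), with STAT5 targets at 0.0580. At least 1 list held 7 of the 11 called genes: CISH, MYC, EGR1, MSMO1, GFI1B, DNAJB4 and TNFAIP3. MYC belongs to 3 lists. Members called with the mean-dependent variance numbered 45.

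**Figure D2:**
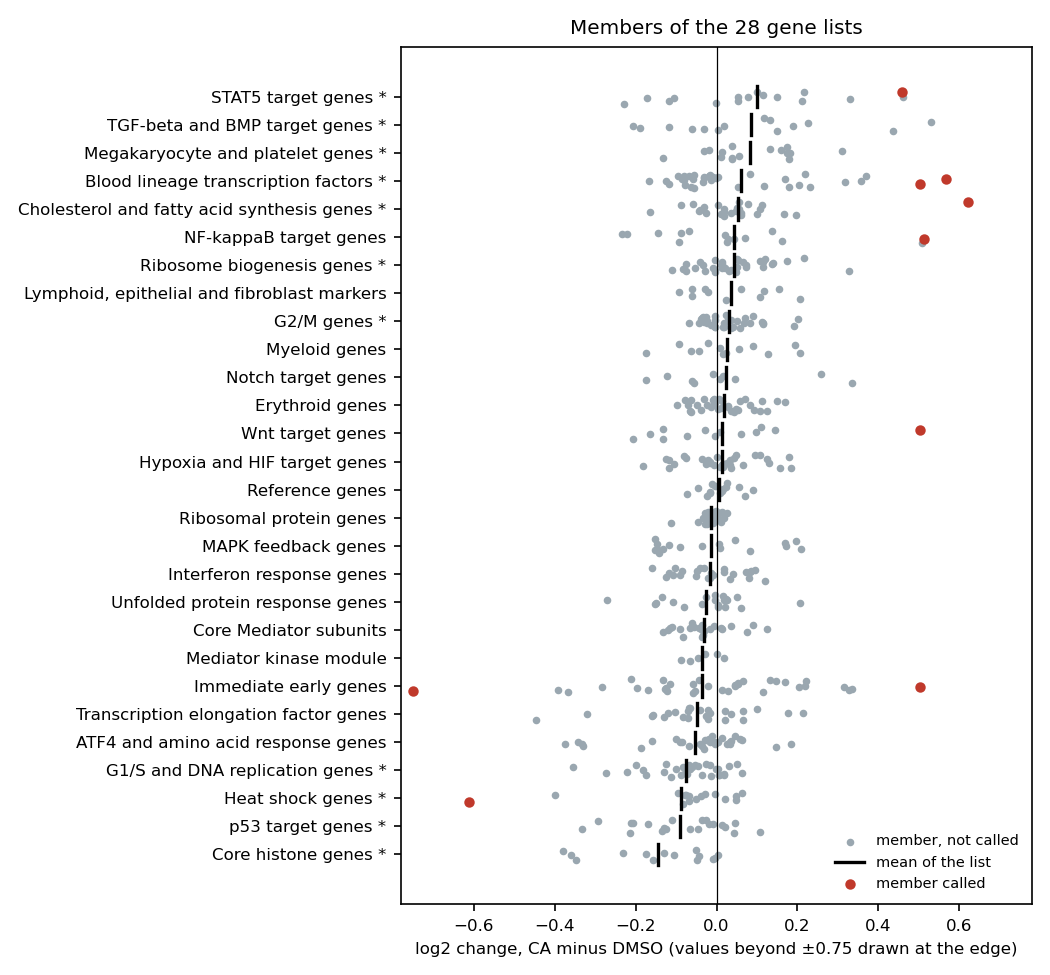
Log2 change (CA minus DMSO) of each measured member of the 28 lists, called members in red and others in grey, with the mean of the list as a black bar; an asterisk marks an adjusted p under 0.05 by camera with its preset correlation, and EGR1 is drawn at the left edge. Core histone genes lie lowest, at a median of -0.12, and STAT5 target genes highest, at 0.09; scaling to the exogenous controls moves every point right, by 0.18 with their 3' probe sets, which takes the histone median to 0.07, and by 0.04 with their 5' probe sets, which takes it to -0.07.

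Among the lists that lay higher, STAT5 target genes had the smallest p (adjusted p = 0.000102 by camera, adjusted p = 0.175 with an estimated correlation). STAT5 is the transcription factor activated by BCR-ABL1 in these cells. Of 16 measured members 1, CISH, was called and 4 passed when adjusted over the list alone, all of them upward: CISH, the kinase genes PIM1 (0.46) and PIM2 (0.22), and SOCS1 (0.33). The other 12 did not pass, and the median of the list was 0.09. Of the 16 members, 11 had fitted rises and 5 fitted falls, and the 9 at p under 0.05 included falls. The call held without each array in turn, at adjusted p between 3.96e-05 and 0.00555.

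Transcription factors of the blood lineages moved in part. Of 35 measured, MYC and GFI1B were called, and 8 passed when adjusted over the list alone, all upward. The other 6 were MYB (0.37), LMO2 (0.36), MEF2C (0.32), NFE2 (0.23), TAL1 (0.22) and GATA2 (0.18), regulators of blood stem cells, red cells and platelets. These 8 were also the members called with the mean-dependent variance. The list lay higher by camera (adjusted p = 0.0115; adjusted p = 0.175 with an estimated correlation) and by its mean of 0.06, while its median was -0.02, since 21 members had fitted falls. Without DMSO array 3 its adjusted p was 0.0533, and with no filter on dim probe sets it was 0.0683.

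Of 26 measured genes of cholesterol and fatty acid synthesis, 2 were at p under 0.05, which equals the median of matched random lists. MSMO1 was called, and SQLE (0.20), the squalene epoxidase gene, passed over the list alone. The list was higher by camera at an adjusted p of 0.0115 (adjusted p = 0.460 with an estimated correlation), with 19 fitted rises and 7 fitted falls. Without CA array 1 that value was 0.107, and without DMSO array 3 it was 0.0533. For TGF-beta and BMP targets, 0 of 14 were called and 6 were at p under 0.05. Adjusted over the list alone, TGIF1, ID2 (0.44) and BAMBI (0.19) passed upward, and CDKN1A (-0.21) and SMAD6 (-0.19) downward. Of these, BAMBI and TGIF1 are known as inhibitors of TGF-beta signalling and SMAD6 as an inhibitor of BMP signalling. The list gave an adjusted p of 0.0295 by camera (adjusted p = 0.460 with an estimated correlation), and its highest value with an array left out was 0.328, without CA array 1. It was also above the threshold without DMSO array 1 (0.0704) and DMSO array 3 (0.0645), and with centring (0.0637), array weights (0.0698) and 3' control scaling (0.445).

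Ribosome biogenesis genes lay higher (adjusted p = 0.00357; adjusted p = 0.175 with an estimated correlation) with 0 of 35 called and 6 at p under 0.05. Over the list alone POLR1G (0.33), a subunit of RNA polymerase I, and PNO1 (0.22), an assembly factor of the small ribosomal subunit, passed, and NPM1, the brightest member, changed by 0.04. Ribosomal protein genes themselves showed a median of -0.01 with 0 of 30 called and 0 at p under 0.05, and RPS23 changed by -0.01. Megakaryocyte and platelet genes were higher by camera (adjusted p = 0.0115; adjusted p = 0.175 with an estimated correlation), with 13 of 16 fitted values above 0, 0 called and 2 at p under 0.05. RAB27B had 0.17, TUBB1 0.16 and SRGN, the brightest, 0.01, and the adjusted p of the list was 0.0505 without CA array 1, 0.106 with no filter, 0.0734 with the filter at the 75th percentile and 0.202 with 3' control scaling. The G2/M list (adjusted p = 0.0288; adjusted p = 0.515 with an estimated correlation) had 0 of 35 called, 3 at p under 0.05 and a median of 0.02. CENPE had 0.19, TPX2 had 0.12 and CDK1 -0.01, and the list was above the threshold without DMSO array 1 (0.0946), DMSO array 3 (0.147), CA array 1 (0.168) or CA array 2 (0.0616), with no filter (0.0738), with array weights (0.0547) and with 5' control scaling (0.0885).

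Core histone genes were the list with the strongest shift, and it was downward (adjusted p = 2.32e-05; adjusted p = 0.175 with an estimated correlation). Of 14 measured, 13 had a fitted fall, 0 were called, 7 were at p under 0.05, and 6 passed when adjusted over the list alone. These were H2BC21 (-0.38), H2BC4 (-0.36), H3C2 (-0.35), H2AC6 (-0.23), H2AX (-0.17) and H2AC8 (-0.16). The exception was H2AZ1, a variant histone made throughout the cell cycle, at 0.00. The median was -0.12 on the RMA scale, 0.07 after 3' control scaling and -0.07 after 5' control scaling. The call held without each array in turn, at adjusted p between 1.40e-05 and 0.000382. With the mean-dependent variance 4 members were called, all downward: H2BC21, H2BC4, H2AC6 and H2AX.

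Genes of the G1/S transition and DNA replication also lay lower than other genes (adjusted p = 0.000293; adjusted p = 0.182 with an estimated correlation). None of 33 was called and 7 were at p under 0.05. CDT1 (-0.22), which licenses replication origins, and the transcription factor gene E2F2 (-0.20) passed over the list alone, and TYMS, the brightest, changed by 0.00. The median was -0.06, or 0.12 after 3' and -0.02 after 5' control scaling. Its call held without each array in turn, and its adjusted p was 0.207 with the control ratio as a covariate and 0.0658 with 3' control scaling. The p53 target list was lower (adjusted p = 0.0115; adjusted p = 0.175 with an estimated correlation) with 0 of 21 called and 5 at p under 0.05, and a median of -0.07, or 0.12 after 3' and -0.02 after 5' control scaling. SESN2 had -0.33, PLK3 -0.29 and CDKN1A -0.21, and CCNG1, the brightest, 0.05. With a filter at the 75th percentile its adjusted p was 0.173. Heat shock genes were lower by camera (adjusted p = 0.0221, or adjusted p = 0.460 with an estimated correlation). Of 16 measured, 2 were at p under 0.05, DNAJB4 was called and DNAJB1 (-0.40) passed over the list alone. The median of the heat shock genes was -0.06, or 0.12 after 3' and -0.02 after 5' control scaling. The adjusted p of the list was 0.0533 without DMSO array 3, 0.105 without CA array 2, 0.0537 with the filter at the 75th percentile and 0.0658 with 3' control scaling.

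Immediate early genes went both ways. Of 35 measured, MYC and EGR1 were called, and over the list alone 8 passed upward and 5 downward. Upward were MYC, HES1 (0.33), MAFF (0.33), GADD45A (0.32), BTG1 (0.22), TRIB1 (0.22), TSC22D1 (0.20) and SRF (0.17). Downward were EGR1, JUND (-0.39), ZFP36 (-0.37), IER2 (-0.20) and JUN (-0.17). As a set the list did not shift 1 way (adjusted p = 0.424 by camera), and its median of 0.01 and mean of -0.04 differed in sign. However, 15 members had an unadjusted p under 0.05, where random lists of the same signal had a median of 3 and a 95th percentile of 6 (permutation p = 0.0001, the smallest that 10000 draws can give; adjusted p = 0.000933). These random lists draw genes, not arrays, so members that move together can give such an excess. The immediate early list was 1 of 7 with more such members than random lists at an adjusted p under 0.05. The others were STAT5 targets (9 of 16) and core histones (7 of 14), both also at 0.000933, blood lineage factors (10 of 35, adjusted p = 0.00560), TGF-beta and BMP targets (6 of 14, adjusted p = 0.00728), G1/S (7 of 33, adjusted p = 0.0196) and the unfolded protein response (5 of 20, adjusted p = 0.0488).

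Several lists that were not called as sets held single members that passed over the list alone. Among elongation factors, 0 of 25 were called and 5 were at p under 0.05. HEXIM1 and MEPCE (-0.32), both partners of the 7SK RNA that holds P-TEFb inactive, passed downward, AFF1 (0.21), a scaffold of the super elongation complex, passed upward, and CCNH changed by -0.02. Among ATF4 and amino acid response genes, DDIT3 (-0.34) and ATF5 (-0.33) passed downward, 0 of 31 were called with 5 at p under 0.05, and SLC38A2 changed by -0.09. Of 15 NF-kappaB targets TNFAIP3 was called and IL6 passed as well. Of 10 Notch targets HES1 and HEY1 (0.26) passed, 0 were called with 3 at p under 0.05, and the mean was 0.02 against a median of 0.00. The Wnt list had MYC as its only called member of 13, and its median of 0.00 and mean of 0.01 differed in sign. The adjusted p of these 5 lists by camera lay between 0.105 and 0.784, and between 0.460 and 0.787 with an estimated correlation. At the preset correlation, 3 of these lists passed without 1 array. These were elongation factors (0.0265) and the ATF4 list (0.0260) without CA array 1, and the NF-kappaB list (0.0237) without DMSO array 1. Elongation factors also passed with array weights (0.0432) and with the mean over probe sets (0.0351), the ATF4 list with the control ratio as a covariate (0.00967) and the NF-kappaB list with the filter at the 75th percentile (0.0111).

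In the remaining lists 0 members were called. The 25 measured interferon response genes had a median of -0.02 and an adjusted p of 0.981, with 0 at p under 0.05 and IFITM1 at -0.01. The direction given by camera for that list was upward while its median and mean were negative. MAPK feedback genes gave an adjusted p of 0.527, with 5 of 17 at p under 0.05 and SPRED2 at 0.04. Hypoxia genes gave 0.388, with 4 of 34 at p under 0.05 and LDHA at 0.00. For unfolded protein response genes the value was 0.614, 5 of 20 were at p under 0.05, the mean was -0.03 against a median of 0.00, and SEC61B changed by 0.00. For erythroid genes it was 0.141, with 1 of 34 at p under 0.05 and the embryonic globin gene HBE1 at -0.01, and it was 0.0316 with the filter at the 75th percentile and 0.0362 with 3' control scaling. Myeloid genes gave 0.165, with 0 of 13 at p under 0.05 and MS4A3 at 0.06. The reference genes had an adjusted p of 0.529 and a median of 0.01, with 0 of 16 at p under 0.05 and EEF1A1 at 0.01. Markers of lymphoid, epithelial and fibroblast cells gave 0.241, with 2 of 11 at p under 0.05; EPCAM, bright in both groups, was at -0.02.

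The labelling controls differed with the treatment, and so alongside every gene group above. The 3' minus 5' signal of the actin control was 1.45 ± 0.04 (SD, n = 3) in DMSO and 1.21 ± 0.09 in CA, a difference of -0.24 without overlap. For the same measure GAPDH differed by -0.03, with overlapping arrays. The 3' probe sets of the exogenous dap, thr, lys and phe controls differed by -0.14, -0.20, -0.17 and -0.22, each without overlap. Of the 5' probe sets, actin was higher in CA by 0.24 and phe differed by -0.19, both without overlap, while dap (0.10), thr (0.11) and lys (-0.20) overlapped. The exact 2-sided permutation p was 0.1 for each difference without overlap, the smallest that 3 against 3 arrays allow.

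**Figure D3:**
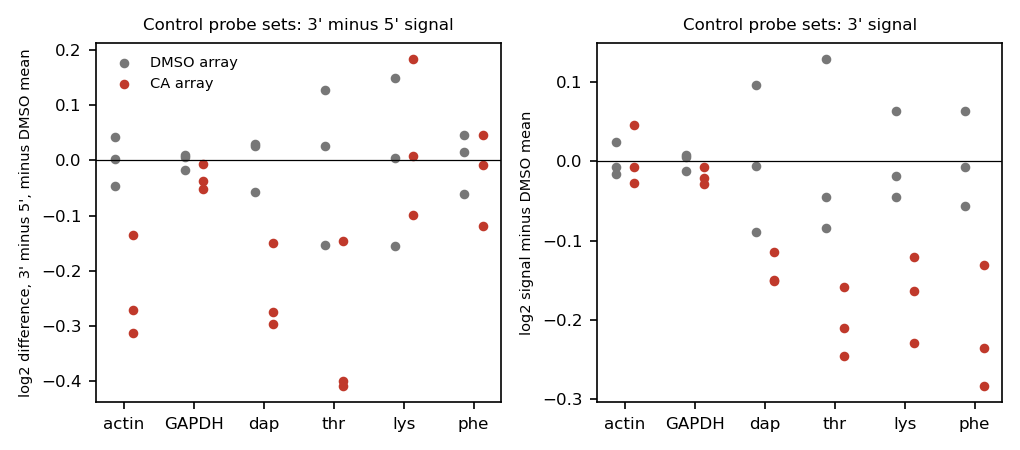
Control probe sets on each array, minus the mean of the 3 DMSO arrays, as the log2 difference between 3' and 5' probe sets (left) and the log2 signal of the 3' probe sets (right), with DMSO arrays in grey and CA arrays in red. Actin and dap separate the groups on the left by -0.24 each, and dap, thr, lys and phe separate them on the right by -0.14 to -0.22.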

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

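The tests on the actin ratio, the covariate fit and the scaling to the exogenous controls were chosen only after the control signals had been seen. The control probe sets were not part of the comparison of genes, and 8 of their values separated CA from DMSO without overlap. The 3' minus 5' value differed by -0.24 for actin and by -0.24 for the exogenous dap control. The 3' signals differed by -0.14 for dap, -0.20 for thr, -0.17 for lys and -0.22 for phe. The 5' signals differed by 0.24 for actin and by -0.19 for phe, and those of dap, thr and lys overlapped. With 3 arrays per group no test for a single outlying array was run.

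A lower 3'/5' ratio of actin may arise from the integrity of the cells' RNA or from the labelling reaction. The ratio of the exogenous dap control differed by -0.24 as well, against a pooled SD of 0.07. That would argue against integrity of the cells' RNA as the whole cause only if dap was added to purified RNA, and the labels do not give the step, so this stays open. A labelling reaction that differed between the groups remains open too, because the ratios point to it only in part. Of the other 5 control transcripts, 1, dap, was lower in CA without overlap. The thr control differed by -0.32 with overlap, while GAPDH, lys and phe differed by -0.03, 0.03 and -0.03. GAPDH and phe, with pooled SDs of 0.02 and 0.07, argue against a reaction that lowered the ratio of every transcript alike. The lys value, with a pooled SD of 0.15, is too imprecise to add much. The test does not decide for a reaction that touched some transcripts more than others, since the controls differ in length and amount. No biological explanation was tested.

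The called probe sets could follow that labelling difference. The covariate was the 3'/5' control ratio, as the mean over actin, dap and thr. In that fit the 26 called probe sets kept a median share of 0.964 of their fitted change (quartiles 0.896 and 1.08). All 26 kept their direction. This cannot decide on a labelling difference, since the actin and dap ratios separated CA from DMSO without overlap. The fit then rests on the spread within groups, which is small in called probe sets and favours a share near 1. A labelling difference therefore stays open. The number called went from 26 to 0 in that fit, in which the median SE went from 0.07 to 0.15 and the total degrees of freedom from 6.56 to 5.60. Which of these ended the calls was not tested. EGR1 went from -1.80 (SE 0.12) to -2.33 (SE 0.17), and TXNIP from -1.17 (SE 0.04) to -1.16 (SE 0.10). An effect of CA, the difference that the design names, remains open as a hypothesis, and no test here decides it.

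Other splits of the 6 arrays into 3 and 3 number 10 with the real split, too few for a share under 0.05. The real split was the 1 with the most calls for each count: 26 probe sets against at most 0 in the others, 26 against 0 at 1.2-fold, 18 against 0 at 1.5-fold, 11 genes against 0, 11 lists against 3, and 285 probe sets against 0 with the mean-dependent variance.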

How the results depend on the processing

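The covariate and both scalings to exogenous controls were chosen after the data were examined, and so was running the shared probe set and mean over probe sets alternatives on results other than, in turn, probe set and gene counts; the rest were planned. Counts are of probe sets, of probe sets changed at least 1.2-fold and at least 1.5-fold, of genes and of list members, which were 26, 26, 18, 11 and 7 in the main setting. With no filter they were 5, 5, 5, 2 and 1, with 54613 probe sets tested. With the filter at the 75th percentile, 162, 119, 93 and 30 were called in these classes other than 1.5-fold, with 13654 tested. The trend gave 285, 165, 157 and 45, and with robust estimation 275, 164, 150 and 44. An adjusted p of 0.1 gave 56, 56, 29 and 16, and 0.01 gave 4, 4, 4, 1 and 0. Leaving out probe sets shared between transcripts gave 1, 1, 1, 0 and 0, with 16602 tested, 13 of the 26 among them; of the 11 genes 5 were tested, 0 were called and all 5 kept their direction. Leaving out each array in turn gave 2 to 5 probe sets at each fold, 1 to 2 genes and 0 to 1 list members, with fewer arrays behind each fit. Numbers do not pair the wells: deviations of equal numbers correlated at -0.07, 0.01 and 0.06, and the limma fit with that block gave 0 in each class, with 2485 probe sets at an unadjusted p under 0.05. The limma fit with the control ratio as a covariate gave 0 in each class, with 1715 at an unadjusted p under 0.05. Scaling to the 3' probe sets of the exogenous controls gave 1888, 1803, 70, 692 and 67; it moves every probe set up, so 1873 of the 1888 were higher, and fitted rises went from 46.5% to 95.7% of probe sets. Scaling to their 5' probe sets gave 39 probe sets and 16 genes, without CISH (adjusted p = 0.0552). Quantile normalisation again, centring, array weights and the mean over probe sets gave counts within 1.5 times the main ones; the first 2 each kept 24 of the 26 probe sets and 9 of the 11 genes, without CISH and RHOH. Of 28 lists, 11 were called; an estimated correlation gave 0 (7 at an unadjusted p under 0.05), fry 7, the covariate 3 (2 of the 11, and the ATF4 list), no filter 8, 3' control scaling 8 (7 of the 11) and 5' control scaling 10. Leaving out probe sets shared between transcripts gave 2, ending 9 calls, the mean over probe sets gave 12, and leaving out each array 6 to 11, the 6 without DMSO array 3. The 11 called genes kept their direction under every alternative in which they were tested, and the 11 called lists kept theirs relative to the other genes. The medians of the 4 lists called lower turned positive with 3' control scaling (core histones to 0.07, G1/S, p53 and heat shock to 0.12). Over the alternatives other than the adjusted p thresholds, single lists stayed on their side of the threshold in 514 cases, lost a call in 60 and gained a call in 9; for named genes these were 1358, 99 and 139, and 0 turned direction with a call on either side. Where no reason is given, the cause was not tested. Probe sets near background are limited by their signal, and changes of small size by the 3 arrays per group.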

Other observations

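The test of histone genes outside the list was chosen only after the fall of the list and of some of these genes had been seen, and the covariate fit after the control signals had been. Outside the list fixed in advance were 20 measured genes of the histone clusters, of which 15 had lower fitted values in CA and 5 higher, with a median of -0.06. H2BC11 had -0.25, H2AC17 -0.23 and H2AC25 -0.20, and H2BC13 had 0.23. None of the 20 was called, and with the mean-dependent variance 2 were, H2BC11 (adjusted p = 0.0484) and H2AC25 (adjusted p = 0.0485). The linker histone variant gene H1-10, outside the clusters, had -0.42 and was called with the mean-dependent variance (adjusted p = 0.00495). Scaled to the exogenous controls, the median of these 20 genes was 0.13 with the 3' and -0.01 with the 5' probe sets of the controls.

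The fit with a mean-dependent variance added genes that no list held. ARRDC4, which like TXNIP encodes an arrestin domain protein and is known as a target of the glucose sensing factor MondoA, had -0.41 (1.33-fold lower, adjusted p = 0.00433 in that fit). PPP1R10 had -0.51 (adjusted p = 0.00194). Upward were SLC30A10, a manganese exporter gene, at 0.58 (adjusted p = 0.0229), BCL2L11, which encodes the cell death protein BIM, at 0.45 (adjusted p = 0.0231), and FOXO3 at 0.27 (adjusted p = 0.0116). These genes were picked after their values were seen.

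A hypothesis is that the lower position of the core histone list may reflect a fall shared by clustered histone genes. For the 20 clustered genes outside the list, the exact 2-sided sign test gave p = 0.0414. This decides nothing: the test was chosen after some of these falls had been seen, it takes rises and falls as equally frequent where 46.5% of all probe sets had a fitted rise, and histone genes, which share sequence and move together, are not independent. Whether the fall extends beyond the list therefore stays open. In the covariate fit the median of the list went from -0.12 to -0.17, and the list stayed called by camera (adjusted p = 0.00942). The median SE of its members in that fit was 0.12, as large as the fall on the RMA scale. The covariate largely follows the groups, so this fit cannot decide on a labelling difference, which stays open. Over its 21 alternatives the adjusted p of the list lay between 1.81e-08 and 0.175. Histone transcripts mostly lack a poly(A) tail, so the part seen by this labelling is not the bulk of them. Whether fewer cells were in S phase was not measured.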
